A study of Mus musculus with 8 samples.

How the data were processed

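Gene expression was measured by RNA sequencing of liver tissue from ICR mice, an outbred strain. Per the labels, a decoction of Psoraleae Fructus (the dried fruit of Psoralea corylifolia) at high dose, or saline, was given into the stomach for 30 days. The labels place 4 libraries in the treated group and 4 in the control group, and give no batch, sex, hour of collection or dose in units of mass. They do not say which animal each library came from, so p-values measure the spread between these libraries. Per the labels' protocols, RNA was extracted with Trizol, poly-A RNA was selected on oligo-dT beads, and libraries were made with a kit that does not mark the strand of origin.

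The deposited table holds raw read counts per gene for each library, together with FPKM values. Per the submitters' processing notes, HISAT2, HTSeq 0.13.5, DESeq2 1.32.0 and the genome build GRCm38 were used, with no role stated for each. The gene annotation release and the strand setting of the counting are not given in the sources used here. Reads from a gene and a partner overlapping it on the opposite strand can therefore not be told apart, and reads of near-identical paralogs or pseudogenes could be split between them. The deposited FPKM of each gene is its count divided by a gene length and by the library total of the same table, as checked on the values. That gene length was recovered from them. The table lists 24547 genes, of which 1620 had no count in any library. Library totals ran from 15864399 to 20159132 counts. Of the gene identifiers, 24540 matched the GENCODE mouse annotation on GRCm38, from which positions, biotypes, exon overlaps and GC content were taken. The table gave 9 symbols in the form of calendar dates, and these were replaced through their identifiers.

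Counts were analysed in R 4.3.3 with edgeR 4.0.16, as laid down before the data were examined. Genes were filtered with filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 12861 genes. TMM factors were applied, and the quasi-likelihood F test with robust dispersion compared treated with control libraries, with an intercept and the group as the only terms. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. Adjusted p-values of genes below come from this test unless another is named. Expression is given as CPM (depth-scaled counts, with TMM factors), as mean ± SD. Fold changes are log2, treated minus control, with the standard error derived from the F statistic.

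For gene groups, 44 lists with 747 different genes were fixed before the data were examined, covering liver pathways, other cell types and signs of tissue handling. Camera of limma 3.58.1 with a preset inter-gene correlation of 0.01 was run on log2 CPM with a prior count of 2 for the 39 lists with at least 3 tested members, with Benjamini-Hochberg adjustment over the lists. Counts of called members are given over all genes tested and adjusted over the list alone. Principal components were taken from the 500 most variable tested genes, and the group difference on component 1 was tested by an exact two-sided permutation over 70 assignments, whose smallest possible p is 0.0286.

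Genes are named by a rule fixed before the data were examined. It takes, per direction, the 12 largest fold changes among called genes with a mean of at least 5 CPM whose treated values all lie on the same side of the control values, leaving out predicted-gene symbols. It adds the 5 most abundant called genes per direction and, per list, up to 4 called members of smallest adjusted p. Where no member was called, the 2 most abundant are given as values. Other genes are said to be chosen after their values were seen, and list members beyond the rule are given to describe a list. Some genes that the rule takes are not reported here.

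The edgeR and camera steps were tested on simulated counts for this comparison. With 12659 genes and 200 of them changed, 5.63% of genes changed 1.5-fold were recovered, 45.9% of those changed 2-fold and 82.4% of those changed 4-fold, and 4.35% of the 92 calls were unchanged genes. Small changes were therefore mostly missed in this simulation. It gave 92 calls against 1184 in the data, where the adjustment allows a larger unadjusted p, and it held no trend with gene length or GC content. Its shares therefore need not hold for these data. No pair of libraries held identical or near-identical counts, since the chi-square per degree of freedom between any pair was at least 32.1.

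Alternatives tried were DESeq2 size factors, library size alone, upper quartile factors, no low-count filter, a stricter filter, non-robust dispersion, DESeq2 1.42.0 with its Wald test, limma-voom with quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes of mean FPKM at least 0.5 and without that filter, a replicate block, stricter thresholds and leaving out each library. For lists, an estimated correlation and the fry test were also run. Added after the data were seen were a correction of each library for gene length and GC content by natural splines with 5 degrees of freedom, the same for length alone, and a fit without the controls numbered 2 and 4.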

Results

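The 4 liver RNA libraries of the group given high-dose Psoraleae Fructus decoction for 30 days (treated) were compared with 4 control libraries, in a series concerned with liver damage by this herbal preparation. The question is which liver genes differ after the treatment. Total counts ran from 15864399 to 19153845 in the controls and from 16398729 to 20159132 in the treated libraries.

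The liver profiles of the groups lay apart on component 1. Component 1, with 41.1% of the variance, ran from 14.8 to 24.1 in treated libraries and from -41.3 to 9.94 in controls, a difference of group means of 35.4 (exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow). Treated libraries resembled each other closely, with correlations of log2 CPM of 0.968 to 0.979, while controls spread over 0.925 to 0.962. Between the groups the correlations were 0.916 to 0.958, so controls resembled treated libraries nearly as much as they resembled each other. Control 4 lay nearest to the treated libraries and control 2 farthest away.

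**Figure D1:**
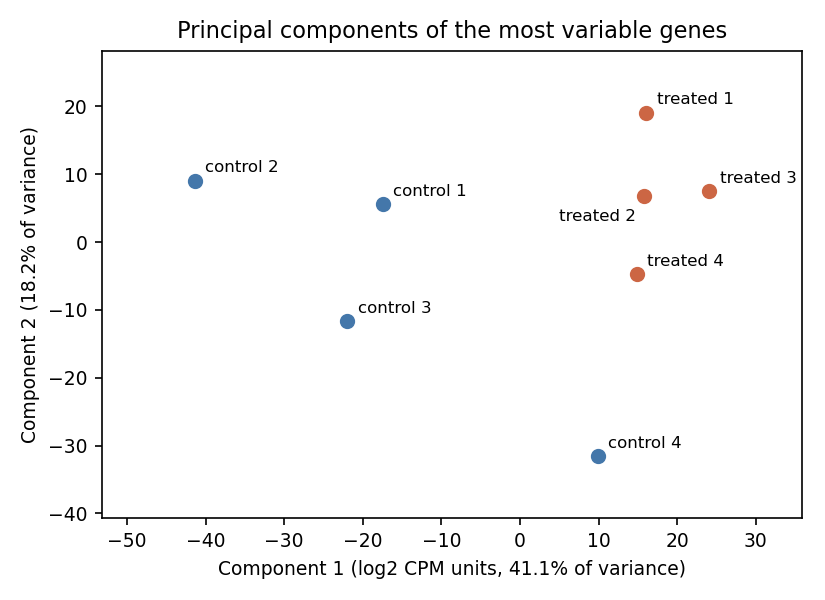
Each point is a library, placed by components 1 and 2 of log2 CPM of the 500 most variable tested genes, with controls in blue and treated libraries in orange. The 4 treated libraries lie at 14.8 or above on component 1 and control 4, at 9.94, is the nearest control.

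Gstp3, a glutathione S-transferase gene (chromosome 19, 4057477 to 4059569), rose from 17.6 ± 18.9 to 623 ± 346 CPM (SD, n = 4 per group; log2 fold change 5.15, SE 0.85, adjusted p = 0.0159). Control 4 was at 45.6 CPM, and without that library the log2 fold change of the gene Gstp3 was 6.24. It has close paralogs, so its level is uncertain where reads were shared. Cyp2a5, a cytochrome P450 of coumarin and nicotine oxidation (chromosome 7, 26835305 to 26843548), rose from 298 ± 78.0 to 1241 ± 310 CPM (log2 2.06, SE 0.25, adjusted p = 0.00501). Sult2a3, a sulfotransferase gene with close paralogs, rose by 2.80 on the log2 scale (SE 0.65), Plekhf1 by 2.37 (SE 0.32) and Atp5k, a subunit of ATP synthase, by 2.31 (SE 0.22). Further genes among the 12 largest rises were Wee1, Rpl22l1, Cyp7a1, Fabp1, Fam213b, Slc16a11 and Rnf5, with log2 fold changes from 1.60 to 2.25. In all, 1184 of 12861 genes were called, 702 higher and 482 lower in treated libraries, and 1136 of them had no overlap between groups. A correction for gene length and GC content, added after the data were seen, ended the calls of 34 of the 80 called genes among those named by the rule or chosen later, and where such a gene is named below it is said to be lost after the correction. In 27 of the 34 the fold change was within 1.5 times of the uncorrected one, so the lost call alone does not show that length or GC content made the difference. Values after the correction are given as corrected log2. Over all tested genes the non-overlapping share was 18.9%, against 2.86% by chance. The count moved to between 183 and 2330 when single libraries were left out, and was 183 without treated library 3 and 2330 without control 4. Without controls 2 and 4, a choice made after the data were seen, it was 1075.

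**Figure D2:**
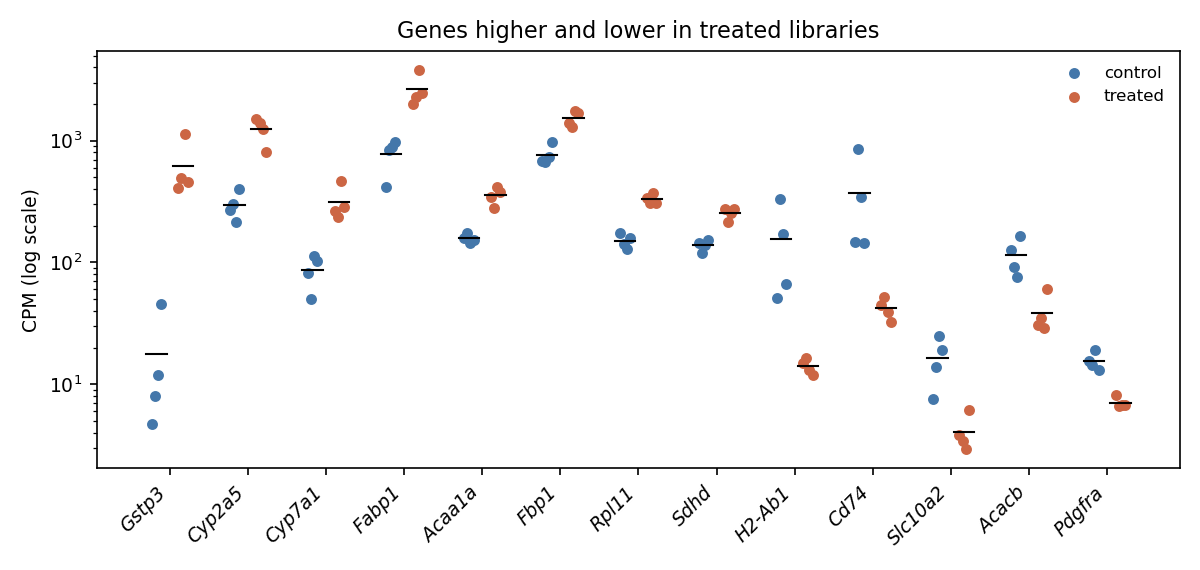
Points are CPM of single libraries on a log scale for 13 genes, with controls in blue, treated libraries in orange and a black bar at each group mean (n = 4). No gene shown has overlapping groups, which the naming rule required of the largest rises and falls. The controls of H2-Ab1 and Cd74 are widely spread.

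Cyp7a1, the rate-limiting enzyme of bile acid synthesis from cholesterol (chromosome 4, 6265612 to 6275633), rose from 86.5 ± 27.5 to 314 ± 104 CPM (log2 1.86, SE 0.29, adjusted p = 0.00942) and was the only called member of 13 in its list, over all genes and adjusted over the list alone. Slc10a2, an ileal-type sodium-dependent bile acid transporter, fell from 16.4 ± 7.43 to 4.05 ± 1.41 CPM. None of 17 genes of bile acid transport and FXR response was called, by either adjustment, and the uptake carriers stood at 1497 ± 472 against 1528 ± 292 CPM for Slco1b2 and 674 ± 174 against 656 ± 36.4 for Slc10a1. Neither list passed camera (adjusted p = 0.525 and 0.228).

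Fabp1, the liver fatty acid binding protein, rose from 777 ± 246 to 2643 ± 811 CPM (log2 1.77, SE 0.30, adjusted p = 0.0114), and the peroxisomal thiolases Acaa1a and Acaa1b rose by 1.17 (SE 0.15) and 1.12 (SE 0.23). These thiolase genes are paralogs and could share reads. With Acadvl, 4 of 29 genes of fatty acid oxidation rose and none fell (5 higher and 1 lower adjusted over the list alone), of which Acaa1b (corrected log2 0.84, uncorrected 1.12) and Acadvl (0.40, uncorrected 0.48) were lost after the correction. Acacb, an acetyl-CoA carboxylase, fell from 115 ± 40.3 to 38.7 ± 14.5 CPM (adjusted p = 0.0204), the only called gene of 16 genes of fatty acid synthesis by either adjustment. Pparg and Apoa4 rose and Mttp, which loads lipid onto lipoproteins, fell by 0.52 (SE 0.13), 3 called of 15 genes of lipid uptake and export (3 higher and 2 lower adjusted over the list alone), with Mttp lost after the correction (corrected log2 -0.36). None of 24 genes of cholesterol synthesis was called by either adjustment, and Sc5d stood at 177 ± 133 against 132 ± 16.1 CPM. Fbp1, Gys2 and Pcx rose among 13 genes of glucose metabolism (3 higher and 2 lower adjusted over the list alone), Fbp1 of gluconeogenesis from 764 ± 140 to 1535 ± 228 CPM (adjusted p = 0.0142), and Gpt, which encodes alanine aminotransferase, rose among 21 genes of the urea cycle and amino acids (0 adjusted over the list alone). Of these Pcx (corrected log2 0.37, uncorrected 0.51) and Gpt (0.59, uncorrected 0.83) were lost after the correction, as was Gys2 with no loss of fold (0.75, uncorrected 0.73, adjusted p = 0.0577), and Pcx was called in 0 of the 8 fits with a library left out. Insig2, a brake on sterol synthesis, fell from 670 ± 211 to 242 ± 97.0 CPM, and was lost after the correction with little change of fold (corrected log2 -1.38, uncorrected -1.47, adjusted p = 0.0528). None of these lists passed camera with all libraries, the lowest adjusted p being 0.11 for fatty acid oxidation. The mean log2 deviation in control 4 was 1.23 for cholesterol synthesis, 1.60 for fatty acid synthesis and -1.23 for fatty acid oxidation. Without control 4 the list cholesterol synthesis and SREBP2 targets passed upward (median log2 change 0.51 against 0.031 with all libraries, adjusted p = 0.000119), as it did without controls 2 and 4 (adjusted p = 6.73e-05). The list PPARa targets and fatty acid oxidation passed upward without control 2, control 3 or treated library 2 (adjusted p = 0.0382, 0.0131 and 0.0356), and the list urea cycle and amino acid metabolism without control 1 (adjusted p = 0.0282). With an estimated correlation none of these passes held, the adjusted p in the same fits being 0.737 and 0.791 for cholesterol synthesis, 0.893, 0.715 and 0.793 for fatty acid oxidation and 0.784 for the urea cycle.

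Few of the listed targets of the xenobiotic receptors and of NRF2 were called, as were few of all genes tested (1184 of 12861). In the simulation 45.9% of genes changed 2-fold were recovered, so an uncalled gene need not be unchanged. Ahr itself rose by 0.49 (SE 0.13, adjusted p = 0.0464), the only called gene of 7 in its list (1 higher and 1 lower adjusted over the list alone), and Nr1i3, the receptor CAR, rose by 0.85 (SE 0.18) while Aldh1a7 fell by 1.95 (SE 0.47), 2 called of 21 CAR and PXR genes (2 higher and 1 lower adjusted over the list alone), with Aldh1a7 lost after the correction at nearly the same fold (corrected log2 -1.90, adjusted p = 0.054). G6pdx fell by 1.14 (SE 0.24), the only called gene of 24 NRF2 targets by either adjustment. None of 19 listed conjugation enzymes was called by either adjustment, with Gnmt at 1058 ± 332 against 1648 ± 187 CPM. Gstp3, Sult2a3 and Cyp2a5, called higher as given above, are on none of the lists. Of the p53 list Eda2r, Bax and Aen rose, 3 of 19 by either adjustment, though after the correction Bax stood at 0.25 on the log2 scale (SE 0.17, adjusted p = 0.391). Of 22 genes of the unfolded protein response Herpud1 rose and Dnajc3 fell (2 higher and 1 lower adjusted over the list alone), and both were lost after the correction, Herpud1 with little change of fold (corrected log2 1.20, uncorrected 1.27) and Dnajc3 with a smaller one (-0.39, uncorrected -0.60). Camera gave no call for these 6 lists with all libraries, the lowest adjusted p being 0.0699 for the p53 list, which passed in 3 of the 8 fits with a library left out. The CAR and PXR list passed in 1 of these fits. None of these passes held with an estimated correlation in the same fits.

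Of the ribosomal protein, oxidative phosphorylation and antioxidant lists, 12 of 24, 9 of 28 and 3 of 18 genes rose. Rpl11 rose from 151 ± 19.8 to 333 ± 32.3 CPM (log2 1.14, SE 0.14, adjusted p = 0.00501), with Rplp1, Rps16 and Rpl32. Of 24 ribosomal protein genes 12 rose and Rps2 fell, from 266 ± 105 to 90.0 ± 6.89 CPM, and 15 rose and 1 fell adjusted over the list alone. These genes have many processed pseudogenes, which could take part of their reads. Sdhd rose from 138 ± 14.0 to 255 ± 27.6 CPM (adjusted p = 0.00799), and 9 of 28 nuclear-encoded genes of oxidative phosphorylation rose and none fell, 15 adjusted over the list alone. The antioxidant genes that rose were Sod1, Sod2 and Gpx4, and 4 rose adjusted over the list alone. Camera called all 3 lists upward (adjusted p = 3.59e-08, 6.67e-08 and 0.00669), and none held with an estimated correlation (adjusted p = 0.774 for each). In the same libraries fold changes ran with GC content (rank correlation 0.309 across genes) and with gene length (-0.241), the median log2 change being 0.29 in the shortest of 10 equal bins of genes and -0.18 in the longest. After the correction 6 of the 12 ribosomal protein genes and 4 of the 9 genes of oxidative phosphorylation kept their call. It ended the calls of Rplp1 (log2 0.99 before and 0.29 after, adjusted p = 0.27), Rpl32 (adjusted p = 0.0671) and Gpx4 (log2 0.50 before and 0.15 after, adjusted p = 0.507). None of 12 mitochondrially encoded transcripts was called (4 lower adjusted over the list alone), though camera called the list downward (adjusted p = 0.00994, and adjusted p = 0.774 with an estimated correlation), with mt-Co1 at 24788 ± 2950 against 23885 ± 3731 CPM.

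**Figure D3:**
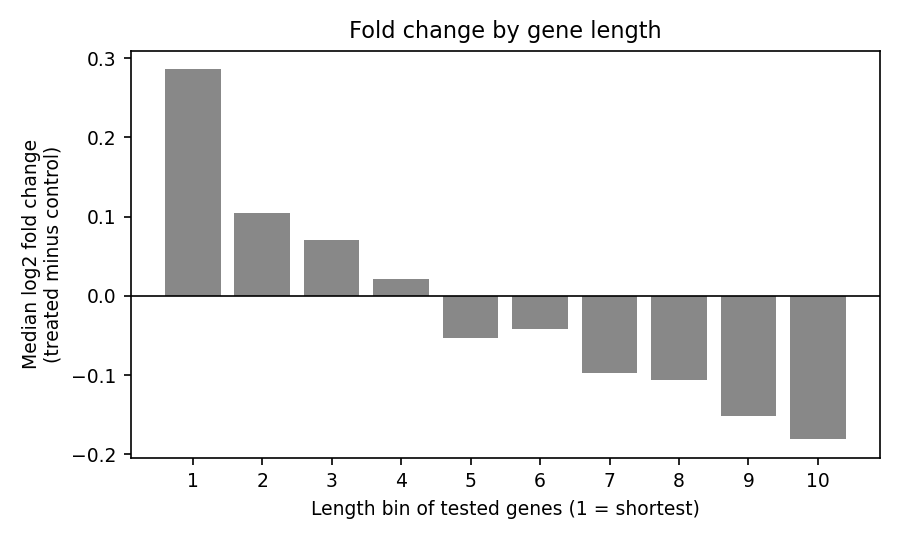
Bars give the median log2 fold change, treated minus control, of tested genes in 10 equal bins of gene length, bin 1 being the shortest. The median falls from 0.29 in the shortest bin to -0.18 in the longest.

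H2-Ab1, an MHC class II chain (chromosome 17, 34257689 to 34269419), fell from 156 ± 131 to 14.1 ± 2.01 CPM (log2 -3.47, SE 0.62, adjusted p = 0.0202), and Cd74, the invariant chain, from 374 ± 336 to 42.0 ± 8.40 CPM (adjusted p = 0.0236). With H2-Aa, H2-DMa and Ciita, the transactivator of these genes, 5 of 7 MHC class II genes fell, and 7 adjusted over the list alone. Each of these 5 calls held in 3 of the 8 fits with a library left out, and H2-DMa and Ciita were lost after the correction at nearly the same fold (corrected log2 -2.97 and -4.03). Control 2 held 42.4 CPM of Ciita, and the log2 fold change of the gene Ciita, -4.06 with all libraries, was -2.57 without control 2. H2-DMa was also highest in control 2, at 54.61 CPM against 6.771 to 16.97 in the other controls. The guanylate-binding protein Gbp2b, Il2rb and Fam111a were also among the 12 largest falls, and Gbp2b (corrected log2 -3.79, uncorrected -3.94) and Fam111a (-1.60, uncorrected -1.85) were lost after the correction. Both were highest in control 2, Gbp2b at 198.1 CPM against 14.7 to 36.15 in the other controls and Fam111a at 16.96 against 3.545 to 7.167. Of 17 macrophage markers Adgre1, Timd4 and Ccr2 fell (7 adjusted over the list alone), and of 8 T and NK cell markers Nkg7 and Cd3g fell (5 adjusted over the list alone). After the correction these calls other than that of Nkg7 were lost, though the falls stayed nearly as large for Timd4 (corrected log2 -1.40, uncorrected -1.48) and Adgre1 (-1.08, uncorrected -1.14) and were somewhat smaller for Ccr2 (-1.21, uncorrected -1.53) and Cd3g (-1.64, uncorrected -1.89). Without control 2, 0 macrophage and 0 T and NK cell markers were called. None of 13 cytokine genes was called and 5 fell adjusted over the list alone, with Cxcl9 at 116 ± 151 against 8.93 ± 3.45 CPM. None of 30 interferon-stimulated genes was called by either adjustment, though their list passed camera in 3 of the 8 fits with a library left out (none with an estimated correlation), and Iigp1 stood at 1365 ± 1629 against 476 ± 74.4 CPM with 3787 CPM in control 2. Camera called the MHC class II, macrophage, T and NK cell and cytokine lists downward (adjusted p = 0.000246, 0.00051, 0.00656 and 0.0081), and none held with an estimated correlation (adjusted p = 0.774 for each). Neutrophil and B cell lists had no called member by either adjustment, with S100a9 at 2.97 ± 2.18 against 4.44 ± 2.39 CPM and Ighm at 7.03 ± 0.71 against 6.83 ± 1.23 CPM.

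Of 20 clock genes 3 fell and 2 rose. Arntl, a core activator of the clock (chromosome 7, 113207465 to 113314126), fell from 22.8 ± 8.66 to 4.38 ± 1.86 CPM (log2 -2.38, SE 0.37, adjusted p = 0.00993), and Npas2 fell from 5.76 ± 3.89 to 0.39 ± 0.11 CPM. Per2 rose from 11.6 ± 3.15 to 26.0 ± 5.80 CPM (adjusted p = 0.0185) and Wee1 from 4.17 ± 2.22 to 19.9 ± 8.39 CPM. Cry1 also fell, a call lost after the correction, and 4 fell and 5 rose adjusted over the list alone. Camera called the list (adjusted p = 0.0346), which was lost with an estimated correlation (adjusted p = 0.774) and held in 6 of the 8 fits with a library left out. Dbp, chosen after its values were seen, stood at 59.9 ± 19.0 CPM in treated libraries and at 35.6 CPM in control 4, but at 2.04 CPM or less in the other controls.

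**Figure D4:**
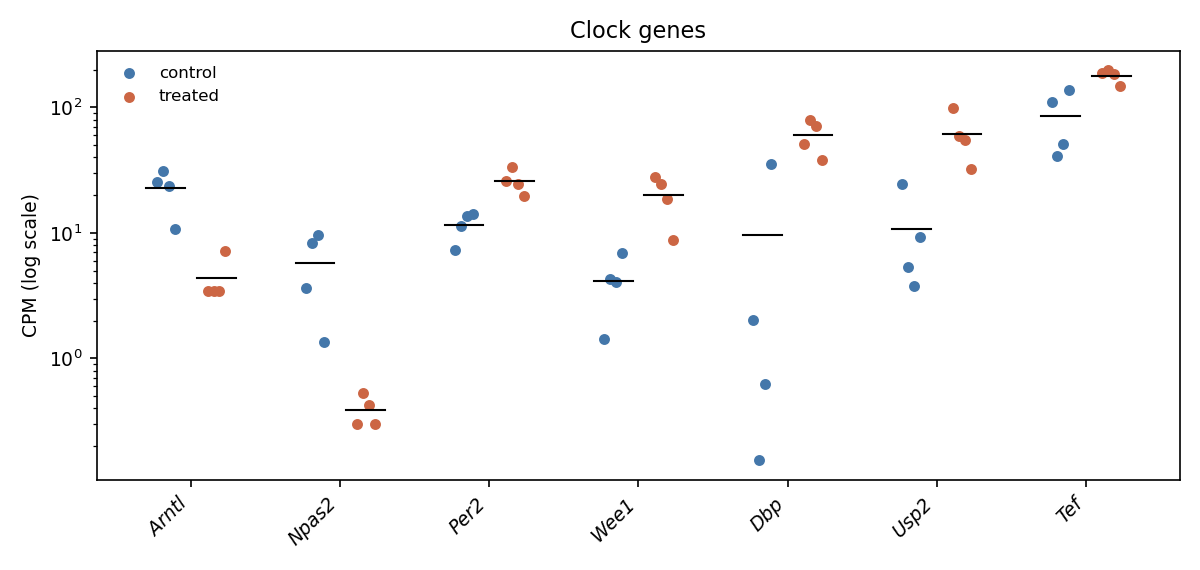
Points are CPM of single libraries on a log scale for 7 clock genes, with controls in blue, treated libraries in orange and a black bar at each group mean (n = 4). Arntl and Npas2 are lower and Per2 and Wee1 higher in treated libraries, and the control point of Dbp at 35.6 CPM is control 4.

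Among other liver and cell type genes, Pdgfra of stellate cells fell from 15.6 ± 2.59 to 7.04 ± 0.71 CPM (adjusted p = 0.00666). It was the only called gene of 19 (3 lower adjusted over the list alone). Pecam1 and Tek fell among 17 genes of sinusoidal endothelium (6 lower and 1 higher adjusted over the list alone). Rnf43 rose among 18 pericentral genes (0 adjusted over the list alone). Aldh1b1 rose and Ctsc fell among 16 periportal genes, and Apoe and Cebpa rose among 21 hepatocyte genes, with equal counts adjusted over the list alone. Tek, Rnf43, Aldh1b1, Ctsc, Apoe and Cebpa were lost after the correction. The fold stayed about as large for Rnf43 (corrected log2 0.87, uncorrected 0.93), Tek (-0.71, uncorrected -0.81) and Aldh1b1 (0.97, uncorrected 1.11), and was smaller for Ctsc (-0.64, uncorrected -0.91), Apoe (0.49, uncorrected 0.78, adjusted p = 0.153) and Cebpa (0.50, uncorrected 0.90, adjusted p = 0.166). Fga, a fibrinogen chain, fell from 5692 ± 605 to 3715 ± 165 CPM, the only called gene of 27 acute phase genes (0 adjusted over the list alone). It was lost after the correction at nearly the same fold (corrected log2 -0.60, uncorrected -0.62, adjusted p = 0.0707). The fibrinogen chains Fgb and Fgg also stood lower, at 5714 ± 124 against 4126 ± 200 and 3990 ± 343 against 2728 ± 133 CPM. They were not called (adjusted p = 0.0773 and 0.0528). Camera called the stellate, endothelial and acute phase lists downward (adjusted p = 0.0433, 0.0472 and 0.0227) and the pericentral list upward (adjusted p = 0.0472). None held with an estimated correlation (adjusted p = 0.906 for endothelium and 0.774 for the others). With a library left out they held in 4, 5, 6 and 4 of 8 fits in this order. The pericentral call was lost after the correction (adjusted p = 0.107) and the stellate call with the replicate block (adjusted p = 0.0529). Of the sex-biased lists C6 fell among 13 male-biased and Ntrk2 among 23 female-biased genes, 1 in each list by either adjustment. Further abundant called genes were Aldh2 and Rdh7, which rose, and Serpina3m, Dnajc3 and Clpx, which fell, as did the pseudogene Serpina4-ps1. Of these Rdh7 (corrected log2 0.60, uncorrected 0.66) and Serpina4-ps1 (-3.28, uncorrected -3.21, adjusted p = 0.054) were lost after the correction at about the same fold, and Dnajc3 as given above. No member was called, by either adjustment, of the heat shock, cell cycle, cholangiocyte, erythroid and immediate early lists, where Hspa8 stood at 1932 ± 670 against 1506 ± 42.8 CPM, Pcna at 20.5 ± 5.20 against 21.2 ± 3.50, Spp1 at 19.2 ± 3.65 against 16.3 ± 8.19, Hbb-bs at 121 ± 59.4 against 186 ± 21.0 and Zfp36 at 59.6 ± 27.2 against 99.6 ± 72.9. Lists of pancreas, adipose tissue, skeletal muscle, intestine and sex chromosomes had 1 tested member each, none called: Cela1, Fabp4, Mylpf, Fabp2 and Xist. Of these Xist was lower adjusted over the list alone. With a library left out the cell cycle list passed camera downward in 3 of 8 fits and the hepatocyte list upward in 2. The erythroid list passed upward in 1 fit and the immediate early list downward in 1. None of these passes held with an estimated correlation in the same fits. The cell cycle list also passed camera with the replicate block (adjusted p = 0.04) and after the correction (adjusted p = 0.046). In total 13 of 39 lists passed camera with all libraries, 5 upward and 8 downward, and none with an estimated correlation or by the directional test of fry, whose test of change in either direction called 16. The preset test is weak evidence here, since 22 of the 35 splits of the 8 libraries into equal groups, the real split included, gave as many called lists.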

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

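The tests of library preparation, of macrophage share and of collection time were chosen after the result was seen, as were the corrections for length and GC content. The reading of the macrophage test was also narrowed after its value was known. Of the 35 splits of the libraries into equal groups, 1, the real one, gave as many called genes: 1184, against at most 3 in another split. A share of 1 in 35 is the smallest that this test can give. Every other split mixes the groups, so any difference between the groups adds to its spread and lowers its count. A chance division of these libraries is therefore unlikely for the gene count, but not excluded. For the lists called by camera, 22 of the 35 splits gave as many as the real 13 and the highest other split gave 18, so chance is not excluded for the list count.

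Single libraries stood apart from the other 3 of their group in 13 of the 324 group values examined, by a gap to the nearest library above Dixon's 95% critical share of the group's range, no more often than the 1 in 20 that chance gives. Treated library 3 lay at 24.12 on component 1, the others at 14.84 to 16.09. The exocrine pancreas mean, which rests on Cela1 alone, was -0.5948 in treated library 1, where Cela1 was at 9.3 CPM against 16.51 to 17.65 in the others. In treated library 2, Serpina4-ps1 was at 13.02 CPM against 2.9 to 3.285, Acadvl at 234.1 against 250.1 to 252.3, Gys2 at 134.8 against 163.3 to 169.7 and Socs2 at 30.91 against 12 to 12.87. Arntl was at 7.167 CPM in treated library 4 against 3.45 to 3.461, and Pdgfra at 8.1 in treated library 1 against 6.569 to 6.749. Among controls, Nr1i3 was at 13.75 CPM in control 4 against 21 to 21.62, Aldh1a7 at 15.98 in control 1 against 64.66 to 70.38, and mt-Co1 at 20410 in control 2 against 25910 to 26870. Cyp4a14, chosen after its values were seen, was at 1.942 CPM in control 4 against 2045 to 2686 in the other controls.

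Of the ribosomal protein and oxidative phosphorylation genes 12 of 24 and 9 of 28 rose, and fold changes ran with gene length and GC content in general. Length here was that implied by the FPKM, and GC content was that of the longest annotated transcript. Neither need be that of the transcripts present in these livers. List medians of 0.603 and 0.395 lay above the upper limits, 0.424 and 0.316, of 10000 random lists matched on length, GC content and expression. These limits may be too narrow, since list members varied together (estimated correlation 0.606 and 0.64) and genes drawn at random need not. The matched genes were also longer, with median lengths of 2013 against 1752 bp and 2405 against 2209 bp. The test therefore cannot decide whether a trend with these properties accounts for all of the rise. The matched lists had medians of 0.252 and 0.154, so part of each rise is shared with genes of like length, GC content and expression. In each library the deviation of genes from their mean log2 CPM over all libraries was rank-correlated with gene length. This correlation differed between groups by -0.326 (exact two-sided permutation p = 0.0286), and library preparation or RNA integrity could have differed with the group. It cannot be told apart from the treatment, since no label gives a batch.

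Of 7 MHC class II genes 5 fell, with the highest values of H2-Ab1 and Cd74 in control 2. Control 2 alone is not the cause, since 5 of 7 members were still called without it, nor is length and GC content the whole cause, since 3 were still called after the correction. The correction ended 2 calls with little change of fold or error, Ciita moving from -4.06 (SE 1.02) to -4.03 (SE 0.99) and H2-DMa from -2.79 (SE 0.69) to -2.97 (SE 0.70). The adjustment became stricter as the count of called genes dropped to 590. The MHC class II mean minus the macrophage mean differed by -1.94, treated minus control (exact two-sided permutation p = 0.0571). On average the MHC class II genes thus fell further than the macrophage markers, but control 1 at -0.601 lay within the treated range. A lower share of macrophages may still contribute. Controls 2 and 3 had the highest MHC class II means (3.439 and 1.894) and T and NK cell means (1.641 and 0.8774), and the test did not cover those cells. Macrophage share and lower expression per cell cannot be told apart by that test, and an effect of the treatment stays open.

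Of 20 clock genes 5 were called. Of 15 clock genes assigned to phases after the result was seen, 15 had a fold change with the sign that lower Arntl sets for a common shift, but only Arntl, Npas2, Cry1, Per2 and Wee1 passed the test, and the change of Nfil3 (log2 -0.15, SE 0.22, adjusted p = 0.67) lay within its error. Length and GC content do not account for this, since 4 of the 5 called genes, all but Cry1, were still called after the correction. Clock genes also differed among the controls, and so varied without the treatment. Control 4 was nearest to the treated libraries in Arntl (10.76 against 23.83 to 31.34 CPM in the other controls) and Npas2 (1.365 against 3.666 to 9.618). For Usp2, chosen after its values were seen, control 1 was nearest, at 24.64 CPM. The hour of tissue collection could have differed between groups. This cannot be told apart from a shift by the treatment, since no label gives the hour.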

How the results depend on the processing

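The corrections for length and GC content and the fit without controls 2 and 4 were chosen after the data were seen. No called gene or list named in the text reversed under any alternative run, and of all 1184 called genes 4 changed sign under the length and GC correction. The 1184 called genes (702 higher, 482 lower) became 2160 (1142 and 1018) with DESeq2, 2088 (1184 and 904) with limma-voom and 322 (261 and 61) with unfiltered FPKM, and 261 or 279 genes were lower with filtered FPKM at a pseudocount of 1 or 0.1. The share of calls that were higher was 59.3%, and ran from 52.5% without control 4 to 81.1% with unfiltered FPKM. A fold of 2 left 403 genes and an adjusted p under 0.01 left 145. Correcting length and GC content left 590 (404 higher, 186 lower), of which 499 were shared with the 1184, and correcting length alone left 264 lower. Without controls 2 and 4 the count was 1075, of which 670 were shared. Leaving out a library gave 183 to 2330 called genes, 147 to 1224 higher and 36 to 1106 lower: 584 without control 2, 397 without control 3, 2330 without control 4, and 460, 460, 183 and 474 without treated libraries 1 to 4. Fewer libraries lower the power, but the rise without control 4 is not of that kind, and the cause was not tested. Each library's deviation in log2 CPM from the gene mean over the 8 libraries was rank-correlated with gene length. This correlation was 0.0259 in control 4, nearest to the treated libraries, and 0.179 to 0.186 in the other controls. It is relative to that mean, so its sign does not say whether long genes were expressed more than short ones. It was lowest, -0.298, in treated library 3, but leaving out treated library 4, at -0.241, gave 474 called genes. Component 1 differed by 33.54 to 48.14 with a library left out, and without a treated library its exact permutation p was 0.0571 to 0.0857. The 13 called lists became 0 with an estimated correlation and 0 with the directional test of fry, where 9 lists had an unadjusted p under 0.05, while its test of change in either direction called 16. With an estimated correlation 0 lists were called in each fit with a library left out. Same-numbered libraries had residual correlations of 0.18, 0.059, -0.012 and 0.07, not all above 0.1, so the numbers were not taken as pairs. With the replicate block 944 genes were called, 781 of them shared with the 1184, and 3 of 8 libraries correlated best with their own number. Of the 80 called genes among those named, 13 were called under every alternative that gave a value. With a library left out, the calls of Aldh1a7, Timd4, Adgre1, Aldh1b1, Rdh7, Rnf43, Sod2 and Tek held in 1 of 8 fits. Those of Ahr, Apoe, Fga, Mttp, Insig2, Herpud1, Gys2 and Gpt, among others, held in 2. Calls that held in all 8 included Cyp2a5, Cyp7a1, Fabp1, Arntl, Npas2, Rpl11 and Pdgfra. The groups of Aldh1a7 and Adgre1 also overlapped.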

Other observations

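The test of neighbouring genes was planned before its result was seen and its form with GC content was added afterwards, while the genes of this part were chosen after their values were seen. Socs2, a suppressor of cytokine signalling, fell from 45.7 ± 4.53 to 17.0 ± 9.27 CPM (SD, n = 4; adjusted p = 0.0265) and Cish, of the same family, from 7.84 ± 2.80 to 2.43 ± 1.56 CPM (adjusted p = 0.0402). Both calls held in 3 of the 8 fits with a library left out, and Cish was not called after the correction for length and GC content, at nearly the same fold (log2 -1.70 after and -1.69 before, adjusted p = 0.0554). Gbp2, an interferon-induced gene, was at 592 CPM in control 2 and at 13.8 to 27.8 CPM in the other controls, and was not called (adjusted p = 0.0974). The clock outputs Usp2 and Tef stood at 10.8 ± 9.54 against 61.2 ± 27.8 CPM and 84.9 ± 46.4 against 179 ± 22.0 CPM and were not called (adjusted p = 0.0528 and 0.0965). Genes linked to the Y chromosome had 0 counts in all 8 libraries, while Xist was counted in each.

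ICR mice are outbred, so inherited haplotypes may differ between small groups and move neighbouring genes together. Of the 1184 called genes, 545 had a gene called in the same direction within 500 kb, leaving out pairs with the same first 3 letters of the symbol, against a median of 462 and a 95th percentile of 495 in 10000 shuffles of the calls within 10 bins of gene length. Leaving out overlapping genes as well gave 535 against a median of 455. Neighbouring genes also share GC content, with which fold changes ran, and shuffles within 100 bins of length and GC content had a median of 507 and a 95th percentile of 538, reaching 545 in 270 of 10000. Part of the excess is therefore shared with genes of like length and GC content. The rest is consistent with the haplotype hypothesis, but GC differences inside bins or neighbouring genes that share regulation could give it too, and the test does not separate these.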
